A study of Homo sapiens with 3 samples.

How the data were processed

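RNA was measured in 3 libraries of NCI-N87, an established human gastric cancer cell line, after transfection with Lipofectamine 2000. Per the labels, 1 library came from cells given a scrambled siRNA and 2 libraries came from cells given an siRNA against FOXP4, a forkhead transcription factor. The knockdown libraries received different siRNAs, called siRNA1 and siRNA2 here as in the labels, so they are 2 reagents and not repeats of 1 treatment. Per the labels' protocols, poly(A) RNA was captured on oligo-dT beads, fragmented, copied with random hexamers and made into NEBNext libraries. Nothing in the labels says whether the libraries came from separate cultures on separate days.

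The authors deposited 1 table of TPM, a read share corrected for transcript length, with 1 column per library and gene symbols as names. Per the submitters' processing notes the genome build was GRCh38. The quantification tool, its version and the gene annotation were not given in the sources used here. TPM forces each library to the same total, so a rise in abundant transcripts lowers the values of all others. The table held 31907 rows. Of these, 26 had names that a spreadsheet had turned into dates, 4 rows shared such names, and 7683 were 0 in every library. The columns summed to 998273 TPM for the scrambled siRNA, 998717 TPM for siRNA1 and 998406 TPM for siRNA2.

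Depth was read from the low values, because TPM times exon length steps by a fixed amount per read. Among values under 2 TPM with at most 10 estimated reads, 92.7%, 92.2% and 92.5% lay within 0.1 of a whole number of reads in the scrambled, siRNA1 and siRNA2 libraries, against 20% by chance. That put the depth at about 18100000, 18300000 and 18800000 reads, an estimate that rests on exon lengths from GENCODE 29. One read on 2000 bases of exon was worth 0.106, 0.110 and 0.108 TPM. The same code returned 15000000 reads from data simulated at 15000000.

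Values were compared as log2(TPM + 1), so folds of low genes are understated. Genes entered with a mean of at least 1 TPM over the 3 libraries, which left 14429, of which 10847 were protein-coding in GENCODE 29. The group comparison used limma 3.58.1 in R 4.3.3, with an intensity trend in the empirical Bayes step and Benjamini-Hochberg adjustment over all genes tested, with a threshold of 0.05. With 2 libraries against 1 there was 1 residual degree of freedom, taken from the spread between the siRNAs, and the lone scrambled library was assumed to vary like them. That spread holds real differences between siRNAs as well as library noise, and p-values measure only the spread between these libraries. On simulated data with the spread seen between the siRNAs, the test recovered 0% of genes changed by a true log2 of 1, 1.5% at a log2 of 2 and 44.1% at a log2 of 4, among 200 changed genes of 14429. With 0.25 of that spread it recovered 85.5%, 99.9% and 100%.

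A rule of size stood beside the test: genes at least 2-fold from the scrambled library, in the same direction, with both siRNAs. The same rule with siRNA1 or siRNA2 as the lone library served as a yardstick. Because both folds share the scrambled library, 3 unchanged libraries were simulated 100 times, or 20 times in each alternative setting. Their noise was drawn from the differences between the siRNAs, which hold real siRNA differences as well as library noise. Simulated counts and covariances may thus lie above what library noise and a shared control would give. For 35 gene lists, the median log2 fold was placed among 10000 random lists of the same size, matched on expression in 20 bins. A list stood apart when it lay under the 2.5th or over the 97.5th percentile on the same side with both siRNAs, and it needed at least 5 measured members. Percentiles describe these libraries and are no p-values. In simulated unchanged data 0.5% of 200 random lists stood apart, and 100% of 20 lists shifted by a log2 of 1 were found. Noise there was independent between genes, so the 0.5% is no error rate for lists whose genes move together.

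Listed symbols were matched to the table directly or through RefSeq synonyms, which were added after a first look had shown that 28 listed symbols stood under older names. Positions, gene types, lengths and GC content came from GENCODE 29 on GRCh38, matched by symbol for 22180 rows and for 85.3% of the genes tested. GC content was that of the longest transcript. The GC trend was removed, where stated, with a lowess curve of each siRNA's fold on GC content, fitted on nuclear genes with a mean of at least 10 TPM. That step took a Spearman correlation of -0.51 imposed on simulated data to 0.01.

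The groups, tests, lists, named-gene rule and main alternatives were fixed before the data were examined. Genes were named by this rule: the FOXP family with YAP1 and WWTR1, the 12 highest and 12 lowest by the smaller of the 2 folds, up to 4 members of each list standing apart, 2 of each other list, and the 5 most different genes each way between siRNAs. Most of the lowest 12 were small RNAs read from few fragments, so protein-coding genes of at least 10 TPM were added to the lowest genes and to the most different genes after the values were seen. Values of some genes that the rule takes are not reported here. Alternatives fixed beforehand were other pseudocounts (0.1 and 5), other scalings (median-of-ratios and quantile), other filters on low values (none and 10 TPM), other limma settings, other fold limits and leaving out each siRNA. Alternatives chosen after seeing the data were protein-coding genes alone, mitochondrially encoded genes left out, and the GC trend removed. A list of heat shock genes and 22 gene families grouped by name were also examined after the data were seen. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.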

Results

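The data were poly(A) transcriptomes of NCI-N87 gastric cancer cells. One library came from cells transfected with a scrambled siRNA, and 2 came from cells transfected with different siRNAs against FOXP4. Estimated depth was close in all 3, at about 18100000 reads with the scrambled siRNA, 18300000 with siRNA1 and 18800000 with siRNA2. The control had no replicate, so folds against it carry no replicate check on that side. Each value below is 1 library unless an SD is given.

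FOXP4 was lower in both knockdown libraries. The gene (ENSG00000137166.14, chromosome 6, 41546426 to 41602384, plus strand, GRCh38) measured 93.9 TPM with the scrambled siRNA, 51.6 TPM with siRNA1 and 36.7 TPM with siRNA2, so 55.0% and 39.0% of the control level remained. On the log2 scale the folds were -0.85 and -1.33, with a mean of -1.09 ± 0.34 (SD, n = 2). FOXP1, the close relative expressed in these cells, measured 33.4, 45.4 and 31.6 TPM, while FOXP2 was listed at 0 in all 3 libraries and FOXP3 stayed below 0.5 TPM. Among the 500 genes nearest in expression, the FOXP4 fold lay at percentile 5.0 with siRNA1 and percentile 4.2 with siRNA2. FOXP4 is GC-rich at 62.9%, and GC-rich genes as a whole were lower in the library labelled siRNA1. With that trend removed the siRNA1 fold was -0.20, at percentile 26.8, and the siRNA2 fold was -1.02, at percentile 5.2, so the siRNA1 library gives only a weak check of its label. In limma the FOXP4 change did not pass (adjusted p = 0.9999).

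**Figure D1:**
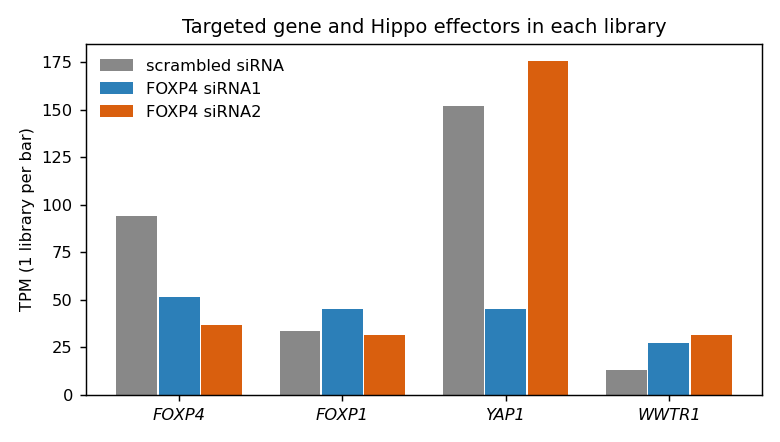
TPM of FOXP4, FOXP1, YAP1 and WWTR1 in the 3 libraries, 1 bar per library and no error bars. FOXP4 was 93.9, 51.6 and 36.7 TPM, and YAP1 was 152, 45.4 and 176 TPM, low with siRNA1 alone.

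The first comparison asked which transcripts went with FOXP4 knockdown. None of the 12 genes highest over the scrambled library with both siRNAs passed limma over all genes tested. CXCL8, the neutrophil chemokine interleukin-8, went from 1.31 TPM to 159 and 334 TPM. EGR1, an immediate early transcription factor, stood at 60.5 TPM in the control and at 1455 and 2305 TPM with siRNA1 and siRNA2. HBEGF, a ligand of the EGF receptor, was 25.97, 245 and 737 TPM, and KLF6, a zinc finger transcription factor, was 113, 1007 and 1588 TPM. PHLDA1 measured 45.2, 438 and 664 TPM. MMP10, a secreted matrix metalloproteinase, measured 3.99, 40.6 and 385 TPM. FOS, FOSB, EGR2, the small GTPase gene ARL14 and the non-coding LINC00659 and SPRY4-IT1 completed the 12 highest. SPRY4-IT1 lies within SPRY4, so its reads could not be told from those of its host. The control value of CXCL8 rested on about 14.0 estimated reads, that of EGR2 on 8.0 and that of ARL14 on 5.0.

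The transcription factors CDX2, SOX2, SP5 and GATA5 measured lower with both siRNAs, and none passed limma over all genes tested (adjusted p = 0.9999). CDX2, the intestinal homeobox factor, measured 161 TPM in the control and 54.7 TPM with siRNA1, and its log2 folds were -1.54 and -3.02. SOX2, a stomach and progenitor factor, measured 59.5, 20.8 and 6.36 TPM. SP5, a target of Wnt signalling, measured 521, 170 and 39.8 TPM, and GATA5 48.4, 15.1 and 12.1 TPM. KIF20A, a kinesin of late mitosis, measured 88.0, 23.7 and 5.45 TPM. HPDL was 75.6, 13.8 and 12.3 TPM. GATA5 and HPDL were among genes named after their values were seen, as were FZD2 (56.1, 17.4 and 13.9 TPM), IGFBP5 (45.2, 13.9 and 8.71 TPM), CLIC3 (58.7, 14.4 and 10.1 TPM), POLD1 (109, 36.7 and 31.9 TPM) and HSPA1B (58.3, 17.4 and 15.8 TPM). Several of these were GC-rich, and with the GC trend removed the siRNA1 folds were smaller, -0.76 in place of -1.61 for SP5 and -0.93 in place of -1.61 for GATA5.

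By the fixed rule the lowest 12 genes included 10 small or non-coding transcripts and 1 T cell receptor segment, among them RNU7-165P, MIR3164, RNU6-1157P, SNORD20, SNORD11B, MIR4449, SCARNA3, AC004000.1 and TRAV39. Each of the 11 was listed at 0 with both siRNAs. In the control, SNORD20 rested on 3.0 estimated reads and AC004000.1, the best covered of those with a known length, on 16.7. For those with the fewest reads a loss was not detectable at this depth.

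Across all 14429 genes, limma called 0 genes at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 428 genes, where 721.5 were expected by chance, and the smallest adjusted p was 0.9999. Other settings gave other counts. The limit on a gene's own spread given below for the fit at 10 TPM holds for the fit on protein-coding genes too. Limma called 92 of 10847 protein-coding genes, and 9 of 14598 genes with mitochondrially encoded genes left out and TPM rescaled. With a mean of at least 10 TPM it called 93 of 9129 genes, 84 higher and 9 lower, with CXCL8, MMP10 and EGR1 first among the higher. In the fit at 10 TPM all genes shared 1 variance trend and a gene's own spread did not enter, and the same fit with siRNA2 as the lone library, a grouping the design does not contain, called 336 genes, and with siRNA1 as the lone library 0. The 9 lower genes included SP5, KIF20A, CDX2, HPDL, GPX2, PRR15L, TRAV41 and SOX2.

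By size alone, 363 genes were at least 2-fold higher and 343 at least 2-fold lower with both siRNAs. CXCL8, EGR1 and HBEGF were among the 64 that were at least 4-fold higher, and 48 genes were at least 4-fold lower. Simulated unchanged libraries sharing a control gave 460.4 and 464.9 genes at 2-fold, and 38.6 and 39.1 at 4-fold. Their noise came from the differences between the siRNAs, so these simulated counts may be too high. Observed counts below them do not exclude shared changes. Taken singly, siRNA1 and siRNA2 had 760 and 993 genes at least 2-fold higher and 866 and 1902 lower, and independent lists of those lengths would share 52.3 and 114.2 genes. With siRNA1 as the lone library 502 genes met the 2-fold rule, and with siRNA2 as the lone library 1397 did, against the 706 found with the scrambled library alone. Among genes of at least 10 TPM the 4-fold genes were 43 higher and 3 lower, where unchanged libraries gave 13.4 and 12.95. The same rule there gave 47 higher and 45 lower with siRNA2 as the lone library, and 2 and 1 with siRNA1. With the GC trend removed, the 2-fold rule over 12302 genes gave 282 higher and 117 lower, against 271.9 and 269.0 simulated.

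Of 30 fixed lists with enough measured members, 1 stood apart as higher and 1 as lower with both siRNAs. The higher list held MAPK feedback regulators and immediate early genes, which are switched on within minutes of ERK and stress kinase signalling. Its 22 measured members had a median log2 fold of 1.97 with siRNA1 and 2.93 with siRNA2, and 19 were higher with both. JUN measured 146, 797 and 1635 TPM, ATF3 23.2, 191 and 320 TPM, and DUSP6, an ERK phosphatase, 96.4, 688 and 791 TPM. DUSP1, a phosphatase of stress kinases, measured 13.3, 76.1 and 836 TPM. MYC was lower with both, at 254, 156 and 197 TPM, and SPRY1 was split, at 36.1, 53.7 and 14.2 TPM. Limma results for lists refer to the 14429 genes unless a mean of at least 10 TPM is named. Adjusted over the list alone, 15 members rose in limma, from EGR1, FOS, FOSB and PHLDA1 (adjusted p = 0.00375) to DUSP1 and SPRY2 (adjusted p = 0.0387), and over all genes tested 0 did. In the fit at 10 TPM, where a gene's own spread did not enter, 13 members rose over all genes. The list's median lay above all 10000 random lists with either siRNA, at percentile 100.

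The lower list held genes of the G1/S transition and DNA replication. Its 28 members had medians of -0.44 and -0.98, and 22 were lower with both siRNAs. MCM5 measured 62.5, 20.3 and 14.1 TPM, GINS2 24.0, 11.9 and 6.22 TPM, MCM2 127, 63.1 and 43.9 TPM, and MCM6 174, 81.0 and 71.8 TPM, while CDC6 was higher with both at 64.0, 81.6 and 75.3 TPM. No member passed limma, adjusted over the list alone or over all genes (smallest adjusted p over the list alone 0.384). Genes of G2/M and mitosis had medians of -0.24 and -1.0 over 30 members, with PLK1 at 93.5, 43.2 and 26.9 TPM. That list missed the limit with siRNA1, at percentile 2.66.

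NF-kB and inflammatory genes had medians of 0.21 with siRNA1 and 1.53 with siRNA2 over 17 measured members, and the list did not stand apart. With the trend of folds on GC content removed, it stood apart as higher, with medians of 0.57 and 1.96 over 16 members. PTGS2, which encodes cyclooxygenase-2, measured 9.999, 66.4 and 113 TPM and CXCL1 4.75, 28.1 and 28.1 TPM. CXCL8, PTGS2 and CXCL1 rose in limma when adjusted over the list alone, and 0 did over all genes. CXCL8 and PTGS2 rose over all genes in the fit at 10 TPM. The receptor tyrosine kinase list had medians of 0.41 and 0.01 over 15 genes. EGFR in that list measured 35.0, 79.8 and 351 TPM, and HBEGF was its 1 member to rise when adjusted over the list alone (adjusted p = 0.0367). HBEGF and EGFR rose over all genes in the fit at 10 TPM.

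Single genes of stress, survival and invasion stood well above the control. The unfolded protein and integrated stress response list had medians of 0.17 and 0.35 over 25 genes. Its members PPP1R15A, at 185, 920 and 2611 TPM, and DDIT3, at 58.1, 269 and 531 TPM, stood well above that median. Among apoptosis regulators, with medians of 0.21 and 0.39, the survival factor MCL1 measured 382, 1780 and 4097 TPM and the pro-death PMAIP1 33.6, 147 and 212 TPM. Integrin, laminin and migration genes had medians of 0.22 and 0.63, with MMP1 at 996, 4458 and 12240 TPM. GDF15, in the p53 target list, measured 1012, 3193 and 11710 TPM, though that list had medians of -0.04 and -0.32. Over the 14429 genes none of these lists stood apart with both siRNAs, and no member of them passed limma adjusted over the list alone. With a mean of at least 10 TPM the apoptosis list stood apart as higher. Over the list alone 3 stress response, 2 apoptosis, 3 integrin and 2 p53 members then rose in limma, and PPP1R15A, DDIT3, MCL1 and PMAIP1 were among those that rose over all genes.

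**Figure D2:**
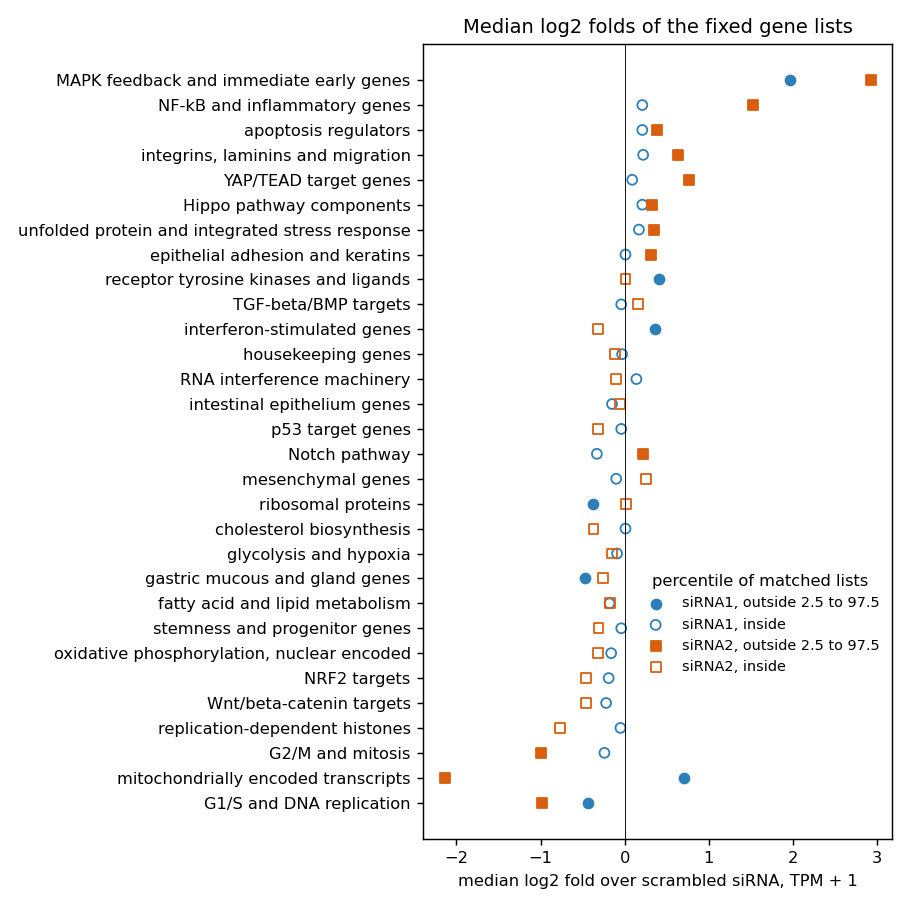
Median log2 fold over the scrambled siRNA, on log2(TPM + 1), for the 30 fixed lists with at least 5 measured members, circles for siRNA1 and squares for siRNA2. Filled symbols lie outside the percentile limits set for matched random lists, as both do for the MAPK list (1.97 and 2.93) and the G1/S list (-0.44 and -0.98).

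Lists of epithelial identity had small or unequal medians. Gastric gland genes had medians of -0.47 and -0.26 over 12 genes, with SOX2 low and ANXA10 at 0.47, 2.91 and 12.98 TPM. The control value of ANXA10 rested on 4.0 estimated reads. Intestinal genes had medians of -0.15 and -0.05 over 16 genes, and Wnt targets -0.22 and -0.46 over 18. Epithelial adhesion genes and keratins had medians of 0.01 and 0.31, where CLDN4 measured 245, 332 and 875 TPM, and mesenchymal genes -0.10 and 0.25. The 26 housekeeping genes had medians of -0.03 and -0.11.

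Metabolic and regulatory lists lay near the control as groups. Medians were 0.01 and -0.37 for cholesterol biosynthesis, -0.18 and -0.17 for fatty acid metabolism, -0.09 and -0.15 for glycolysis and hypoxia, -0.19 and -0.46 for NRF2 targets and -0.16 and -0.32 for nuclear genes of oxidative phosphorylation. They were -0.04 and -0.31 for stemness genes, -0.04 and 0.16 for TGF-beta and BMP targets and 0.14 and -0.10 for the RNA interference machinery. Single members stood apart from these medians. KLF4, a transcription factor of epithelial differentiation, measured 54.8, 108 and 522 TPM. CDKN2B, a cell cycle inhibitor, measured 19.2, 92.7 and 147 TPM, and AGO2, which carries guide RNAs in RNA interference, 25.1, 44.4 and 123 TPM. Over the 14429 genes none of these lists stood apart, and 0 of their members passed limma adjusted over the list alone. With a mean of at least 10 TPM, members of the cholesterol, stemness and TGF-beta lists did.

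Markers of other cell types were few. Only 2 immune markers were measured, CSF1R and LYZ, and LYZ is also made by gastric gland cells (3574, 4401 and 3325 TPM). Only 2 fibroblast and endothelial markers, 4 squamous markers and 0 neuroendocrine markers passed the filter on low values. Of the squamous markers 1 was higher with both siRNAs, S100A2 at 9.76, 26.3 and 115 TPM, 1 was lower with both, KRT13 at 2.55, 1.21 and 0.44 TPM, and 2 were split.

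The series title names YAP1, the transcriptional effector of the Hippo pathway, beside FOXP4. YAP1 (ENSG00000137693.13, chromosome 11, 102110461 to 102233423, plus strand) was low with siRNA1 alone, at 152 TPM in the control, 45.4 TPM with siRNA1 and 176 TPM with siRNA2. Its paralog WWTR1, which encodes TAZ, measured 13.3, 27.6 and 31.3 TPM, log2 folds of 1.00 and 1.18. The Hippo kinase gene LATS1 measured 19.8, 40.2 and 44.1 TPM. Both genes are poor in GC, at 40.9% for WWTR1 and 39.7% for LATS1. Removing the GC trend gave smaller folds with siRNA1, 0.62 for WWTR1 and 0.56 for LATS1. With siRNA2 the folds were then 1.34 and 1.25. The 22 Hippo components had medians of 0.21 and 0.32. The 16 YAP/TEAD target genes had medians of 0.09 with siRNA1 and 0.76 with siRNA2. Of these, CYR61 measured 33.5, 31.9 and 90.6 TPM, CTGF 64.2, 57.2 and 106 TPM and ANKRD1 183, 215 and 318 TPM. Over the 14429 genes no gene of these lists passed limma, adjusted over the list alone or over all genes. With a mean of at least 10 TPM, 2 YAP/TEAD targets passed over the list alone and 1, GADD45A, over all genes (adjusted p = 0.03044).

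The second comparison asked how far the siRNAs gave the same folds. Genes such as CXCL8, EGR1 and FOS were far above the control with both, and CDX2 and MCM5 below it with both. Across genes, which are not independent replicates, the folds had a Pearson correlation of 0.49 and a Spearman correlation of 0.44. Unchanged libraries sharing a control gave 0.50 and 0.48, so these correlations were not above that level. Equal noise in the simulated libraries fixes their Pearson correlation near 0.50, so the comparison cannot show that the siRNAs share only the control. The covariance was 0.297 against 0.319 simulated, a difference of -0.022. The simulated covariance takes its size from the differences between the siRNAs and may be too high. Other settings lay on either side of the simulated 0.50. The Pearson correlation was 0.55 with the GC trend removed, 0.54 with a mean of at least 10 TPM, 0.53 with protein-coding genes and 0.52 with a pseudocount of 5, with covariance differences of 0.019, 0.017, 0.007 and 0.001. It was 0.50 with quantile normalization and without mitochondrial genes, 0.49 without a filter, 0.48 with median-of-ratios rescaling and 0.46 with a pseudocount of 0.1, with differences of -0.012, -0.014, -0.020, -0.038 and -0.11. The Spearman correlation was above its simulated value of 0.47 with the GC trend removed, at 0.50, and below it at 10 TPM, at 0.46 against 0.48. With 1 scrambled library the control could not be split.

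**Figure D3:**
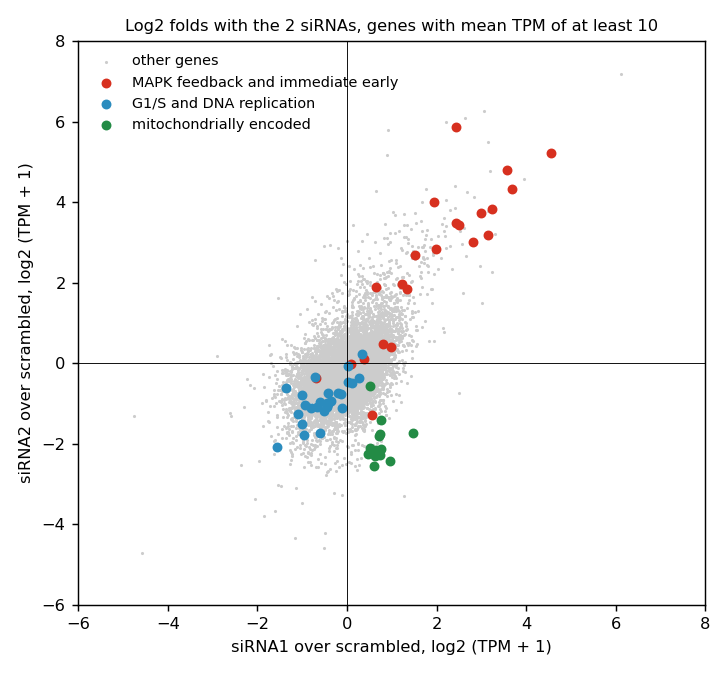
Log2 fold over the scrambled siRNA with siRNA1 (x axis) and siRNA2 (y axis), both on log2(TPM + 1), for the 9129 genes with a mean of at least 10 TPM, 1 point per gene. The MAPK list lies mostly at the upper right (medians 1.97 and 2.93), the G1/S list at the lower left, and the mitochondrially encoded mRNAs at the lower right (medians 0.71 and -2.14).

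The third comparison set siRNA1 against siRNA2. Mitochondrially encoded mRNAs went opposite ways: all 13 were higher than the control with siRNA1 and lower with siRNA2, with medians of 0.71 and -2.14. MT-CO1, a subunit of cytochrome c oxidase, measured 8757, 14580 and 1797 TPM, and MT-CYB 2127, 3230 and 361 TPM. The 13 mRNAs took 5.15% of TPM in the control, 8.05% with siRNA1 and 1.41% with siRNA2. The genes most above siRNA1 with siRNA2 included SPRR2D, a cornified envelope gene (1.61, 3.95 and 144 TPM), PTPRH (8.41, 16.6 and 339 TPM), SERPINB2 (0.70, 6.79 and 108 TPM) and SEMA7A (2.71, 4.84 and 70.7 TPM). Control values rested on 8.0 estimated reads for SPRR2D and 9.0 for SERPINB2. By the fixed rule the genes most above siRNA2 with siRNA1 were small RNAs such as MIR647 and SNORD101, with at most 10 estimated reads. Among genes added after their values were seen, PRR15L measured 73.3, 51.7 and 2.98 TPM, TMEM97 89.1, 82.7 and 8.39 TPM and HKDC1 2.59, 21.4 and 244 TPM.

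Several lists also differed between siRNAs. The 68 ribosomal protein genes had medians of -0.38 and 0.02, interferon-stimulated genes 0.36 and -0.32 over 30 genes, Notch pathway genes -0.33 and 0.22 over 15, and replication-dependent histones -0.05 and -0.77 over 11. The interferon list lay at percentile 29.85 with siRNA2, and its medians were 0.35 and -0.05 after median-of-ratios rescaling. In all, 1842 genes were at least 2-fold higher with siRNA1 and 864 with siRNA2. This split followed the scaling: the median log2 fold of all genes was 0.03 with siRNA1 and -0.24 with siRNA2, and after median-of-ratios rescaling the counts were 1109 and 1384. They were 1055 and 1247 with quantile normalization and 707 and 774 with the GC trend removed, so siRNA2 had the larger count in these 3 settings. With 1 library per siRNA there was no test of these differences.

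Transcript GC content went with the folds, more so with siRNA1. Genes poorest in GC had a median log2 fold of 0.52 with siRNA1 and those richest in GC -0.72, while with siRNA2 these medians were -0.08 and -0.29. Over 8578 nuclear genes of at least 10 TPM, the Spearman correlation of GC content with the fold was -0.68 with siRNA1 and -0.11 with siRNA2. With the GC trend removed the MAPK list had medians of 2.42 and 3.20 and the G1/S list -0.39 and -0.72, both still apart. Other lists then stood apart as well. Lower were genes of G2/M and mitosis (-0.36 and -0.78) and NRF2 targets (-0.29 and -0.24). Higher were NF-kB genes, Hippo components (0.23 and 0.44), integrins, laminins and migration (0.23 and 0.85), the unfolded protein response (0.17 and 0.52) and apoptosis regulators (0.34 and 0.54).

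**Figure D4:**
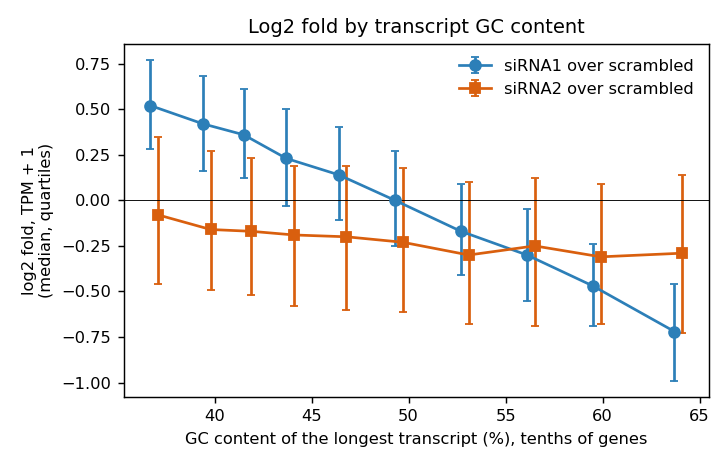
Median log2 fold over the scrambled siRNA, on log2(TPM + 1), in 10 equal bins of genes by GC content (percent, x axis), for nuclear genes with a mean of at least 10 TPM. Bars span the quartiles of genes and the series are offset slightly along x. Medians with siRNA1 go from 0.52 to -0.72 and those with siRNA2 from -0.08 to -0.29.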

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

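The tests on the lone control, on the FOXP4 fold and on YAP/TEAD targets were chosen after the results they weigh had been seen. The list of heat shock genes, the leaving out of mitochondrial genes and the removal of the GC trend were also added after the data had been examined, though before their own results were known.

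Mitochondrially encoded mRNAs were picked out because all 13 moved up with siRNA1 and down with siRNA2, a difference that was not tested. Their median log2 fold of siRNA1 over siRNA2 was 2.81. Nuclear genes in the same range of transcript length had a median of 0.02 and those in the same GC range 0.43 on the same scale, which argues against length or GC bias as the whole cause. Weaker poly(A) selection with siRNA1 than with siRNA2 may contribute. Histone mRNAs without a poly(A) tail lay at percentile 99.78 for siRNA1 over siRNA2, past the level set beforehand. Over the control, their median was -0.05 with siRNA1 (percentile 36.06) and -0.77 with siRNA2 (percentile 2.6). They were thus not raised with siRNA1, where the mitochondrial mRNAs had a median of 0.71. Weaker selection stays open, because the 5 histone genes of at least 10 TPM lay at percentile 49.72 and lower S-phase genes with siRNA2 would lower histones too. An effect of either siRNA on mitochondria also stays open, untested with 1 library each.

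YAP1 was picked out because its transcript was low with siRNA1 and slightly higher with siRNA2, with a log2 fold of siRNA1 over siRNA2 of -1.93, a difference that was not tested. One candidate explanation is that the library labelled siRNA1 holds an siRNA against YAP1 in place of FOXP4. FOXP4 there lay at percentile 5.0 among genes of like expression, and at percentile 26.8 with the GC trend removed, so neither reading could be excluded. YAP/TEAD targets lay at percentile 63.3 with siRNA1 over the control, not low as a loss of YAP1 activity would have them. Their members went both ways around a median of 0.09. For siRNA1 over siRNA2, the contrast that picked out YAP1, their median was -0.74, at percentile 0.0. With siRNA2 over the control they lay at percentile 100, so a loss of YAP1 activity stays open too. An off-target effect of siRNA1 on YAP1, or an effect of FOXP4 loss that siRNA2 masks, stays untested.

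Immediate early and MAPK feedback genes were higher with both siRNAs. Stress at harvest of a kind that also raises heat shock genes is argued against. That list lay at percentile 24.56 with siRNA1 and 3.2 with siRNA2, with HSPA1B and HSPA8 below the control. Of its 12 members 6 were lower with both, 2 higher with both and 4 split. Stress that leaves heat shock genes unchanged stays open, as PPP1R15A and DDIT3 of the stress response list were higher with both siRNAs. GC bias is argued against too, as the smaller list median was 2.42 after removal of the trend. A shift of all TPM values by mitochondrial transcripts could only be small, as these took 6.4%, 10.4% and 1.9% of TPM in the control, siRNA1 and siRNA2 libraries. The smaller list median was 2.03 without them, a result that such small shares all but fixed in advance. Whether the siRNA libraries rose or the control was low in these genes, as culture handling could bring about, cannot be told apart with 1 scrambled library, and an effect of FOXP4 knockdown stays among the open explanations.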

How the results depend on the processing

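Protein-coding genes alone, mitochondrially encoded genes left out and the GC trend removed were chosen after the data had been examined. Against 0 genes called by limma, the count was 93 with a mean of at least 10 TPM, 92 with protein-coding genes alone (82 shared), 9 without mitochondrially encoded genes and 1 with a robust trend, and 0 under the other settings. Genes 2-fold higher and lower with both siRNAs, 363 and 343, became 158 and 121 with a pseudocount of 5, 204 and 143 with a mean of at least 10 TPM, 211 and 177 with protein-coding genes, 931 and 1325 at 1.5-fold, and 64 and 48 at 4-fold. The lower count alone became 521 with a pseudocount of 0.1, 583 without a filter and 117 with the GC trend removed. With either siRNA left out in turn, 760 to 993 genes were higher and 866 to 1902 lower. Lists standing apart as higher, 1 in the main setting, became 2 with quantile normalization (adding the unfolded protein response), 2 with a mean of at least 10 TPM (adding apoptosis regulators) and 6 with the GC trend removed (adding these and the NF-kB, Hippo and integrin lists), and 4 to 9 with either siRNA left out. Lists apart as lower, 1 at first, became 2 with a pseudocount of 5 (adding G2/M), 3 with the GC trend removed (adding G2/M and NRF2 targets) and 3 with either siRNA left out. The MAPK and G1/S lists stayed apart under each setting. Genes higher with siRNA1 and with siRNA2, 1842 and 864, became 708 and 441 with a pseudocount of 5, 1109 and 1384 with median-of-ratios rescaling, 1055 and 1247 with quantile normalization, 707 and 774 with the GC trend removed, 929 and 467 with a mean of at least 10 TPM, 1108 and 514 with protein-coding genes, and 234 and 166 at 4-fold. The siRNA2 count became the larger with either rescaling and with the GC trend removed. The mean FOXP4 log2 fold of -1.09 became -0.61 with the GC trend removed. The correlation between siRNAs ranged from 0.46 to 0.55. Of single values, at most 11 list medians (GC trend removed) and 26 folds of named genes (pseudocount of 5) moved beyond the spread between siRNAs in 1 setting. A fit without either siRNA has no residual degrees of freedom and gave folds only. In the limma fits at 10 TPM and on protein-coding genes all genes shared 1 variance trend and a gene's own spread did not enter. The calls they share are thus no separate support. Beyond that, and beyond constructions that test fewer genes or samples, the cause was not tested. No paired analysis was possible, because there was 1 scrambled library and the labels give no pairing. Depth limits low genes most, as 1 read on 2000 bases was worth 0.106 to 0.110 TPM.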

Other observations

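The gene families here were grouped by name and examined after the data had been seen, 22 in all, and their percentiles come from the same matched random lists as above. Of the 20 with enough members, 3 lay above the upper limit with both siRNAs (KLF genes, serpins and DUSP genes), 1 below the lower limit with both, 1 outside on opposite sides, and 15 did none of these. Over 13 KLF genes, the Krüppel-like factors, the medians were 0.61 and 0.81, and 10 members were higher with both. KLF10 measured 73.3, 257 and 244 TPM in the control, siRNA1 and siRNA2 libraries, KLF4 54.8, 108 and 522 TPM and KLF5 393, 696 and 1548 TPM. The 11 serpins had medians of 0.61 and 1.05, with 7 higher with both, 1 lower with both and 3 split. Those higher with both included SERPINB2, an inhibitor of plasminogen activators, and SERPINB8 at 4.34, 16.2 and 38.4 TPM. With the GC trend removed the medians were 0.63 and 1.09 for KLF genes and 0.47 and 1.21 for serpins. The 17 DUSP genes, some of them in the MAPK list, had medians of 0.41 and 0.33, with 9 higher and 4 lower with both.

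Mitochondrial ribosomal protein genes, which are nuclear, were slightly lower with both siRNAs, with medians of -0.22 and -0.46 over 73 genes and 44 lower with both. With the GC trend removed the medians were -0.21 and -0.23. Zinc finger genes named ZNF went apart, with medians of 0.40 with siRNA1 and -0.39 with siRNA2 over 373 genes. They kept those signs with the GC trend removed, at 0.19 and -0.20. None of the genes in these families passed limma over all genes tested. The heat shock gene DNAJA1 measured 272, 206 and 62.5 TPM and HSPA8 548, 379 and 192 TPM.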
